A study of Danio rerio with 6 samples.

How the data were processed

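Trunk cells positive for both the foxd3 and the sox10 reporter were taken from zebrafish embryos at 36 and 72 hpf, with 3 samples per stage. Per the labels' protocols, each sample held 1750 ± 750 cells, total RNA was extracted with a column kit for small samples, and libraries were made with the Smart-seq v4 kit for ultra-low input. The protocols mention no molecular identifiers and no strand, so PCR copies cannot be removed and transcripts from opposite strands cannot be told apart. All 6 samples were grouped by the stage in their labels.

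Each deposited file lists 52216 Ensembl transcripts with, per the file headers, a length, an effective length, an estimated count and a TPM value. Estimated counts as deposited need not be whole, because a read matching several transcripts is divided among them, and values are written with at most 6 significant digits. The deposited TPM values are the same abundances scaled by effective length to a fixed sum per library. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2 2.1.0, RSEM 1.2.15 and the build danRer10. The file headers use the column names that kallisto writes rather than those of RSEM, and which program made the deposited values is not given in the sources used here. A fragment length was estimated as the median, over transcripts longer than 5000 bases, of length minus effective length plus 1. It was 373, 303 and 375 bases at 36 hpf and 393, 344 and 366 bases at 72 hpf in replicates 1 to 3. This is a median over transcripts and not over fragments.

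The gene tables used here hold no Ensembl transcript identifiers, and 0 of the transcripts could be paired with a gene. Values were therefore analysed per transcript without summing over genes. The 30 gene lists fixed before the data were examined, the sorting genes foxd3 and sox10, and the condition that a named gene has a symbol were not analysed here. The rest of the naming rule was kept: among transcripts past the threshold, without overlap between the stages and with a mean of at least 32 CPM in the higher stage, the largest log2 fold changes were taken in each direction. Of the 8 per direction that the rule allows, 2 are named.

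Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter with stage as the group, and a quasi-likelihood F test with stage as the only term. The filter left 17711 transcripts. Fold changes are 72 hpf over 36 hpf, p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and the standard error of a log2 fold change was its size divided by the square root of F. CPM values are estimated counts scaled to the library's total and not by transcript length. The most abundant transcripts are therefore those with the most counts, and TPM was not used to rank them. A fold against a stage at 0 was computed from pooled counts against a floor of 3 counts over its 3 libraries, and a stage with 1 to 3 counts was given a ratio with an exact 95% counting interval. Shares and detection were compared with exact two-sided permutation tests, for which 3 samples against 3 give 10 splits and no p under 0.1. Transcripts were counted as having unshared reads where their estimated counts were whole in all 6 libraries within 1e-06, which held for 8454 transcripts with 25.1 to 31.8% of the counts. Values of 100000 or more are written without decimals, so for 2 of these transcripts the criterion could not fail in the libraries that reach this level. Similarity used log2(CPM + 1). For detection, libraries were thinned at random to the lowest total of rounded counts, 7123170.

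The tests were tried on simulated counts with the means and library sizes of this comparison, 17711 transcripts and 200 of them changed. Counts were drawn independently with the dispersions that edgeR estimated. They hold no differences in detection between libraries beyond depth, so the error rates need not carry over to the data. edgeR called 0 of 67 transcripts changed 8-fold, 5 of 67 (7.46%) changed 64-fold and 26 of 66 (39.4%) changed 1000-fold, and 0 of 17511 unchanged ones. DESeq2 called 6, 36 and 50 of the same groups and 314 unchanged ones, and limma-voom called 0, 2 and 17 and 3 unchanged ones. edgeR was chosen as the main test before the data were examined and was kept.

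Alternatives fixed beforehand were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom and limma-trend on log2(TPM + 1) with limma 3.58.1, a robust fit, the replicate number as a block, other thresholds and leaving out each library. Added after the data were seen were a test of unshared transcripts only, a minimum of 100 CPM at 1 stage, other minimums for abundant transcripts and other numbers of top transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.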

Results

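RNA was sequenced from trunk neural crest cells of zebrafish, a migratory embryonic population that gives rise to pigment cells, peripheral neurons and glia. The cells carried 2 reporters, an mCherry gene trap at foxd3 and a membrane EGFP transgene driven by sox10, and cells positive for both were collected. Embryos were taken at 36 and 72 hours post fertilization (hpf), with 3 samples per stage, and the single comparison in the design is between these stages. The libraries at 36 hpf held 10520927, 18322110 and 12933945 estimated counts in replicates 1 to 3, and those at 72 hpf held 8502028, 7123251 and 11191844. Nothing in the labels says whether the samples of a stage came from separate clutches or days, so the p-values measure only the spread between these samples, which may be technical. Abundances were given per Ensembl transcript, and the tables used here do not pair the transcripts with genes. Transcripts are therefore described by identifier or length, and the levels of foxd3 and sox10 were not analysed here.

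At 36 hpf a single transcript of 1932 bases held 7.50% ± 0.50 (SD, n = 3) of each library's counts. At 72 hpf the most abundant transcript of each library held 0.691% ± 0.085 (SD, n = 3). The 10 most abundant transcripts held 13.0% ± 0.19 of the counts at 36 hpf and 4.51% ± 0.74 at 72 hpf (SD, n = 3). For the 100 most abundant the shares were 26.6% ± 0.69 and 17.4% ± 2.18 (SD, n = 3). Each of these 3 shares was higher in every library at 36 hpf than in any at 72 hpf, with an exact two-sided permutation p of 0.1, the smallest that 3 samples against 3 allow. The 1932-base transcript enters each of them at 36 hpf, so the 3 shares are not separate results.

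More transcripts reached 10 counts at 36 hpf (15089, 21068 and 20355) than in replicates 1 and 2 at 72 hpf (11511 and 10548), but replicate 3 at 72 hpf reached 18793. The stages overlapped in this measure, with an exact two-sided permutation p of 0.2. After each library was thinned to 7123170 counts, the values were 14419, 18710 and 18821 at 36 hpf and 11338, 10583 and 17957 at 72 hpf.

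**Figure D1:**
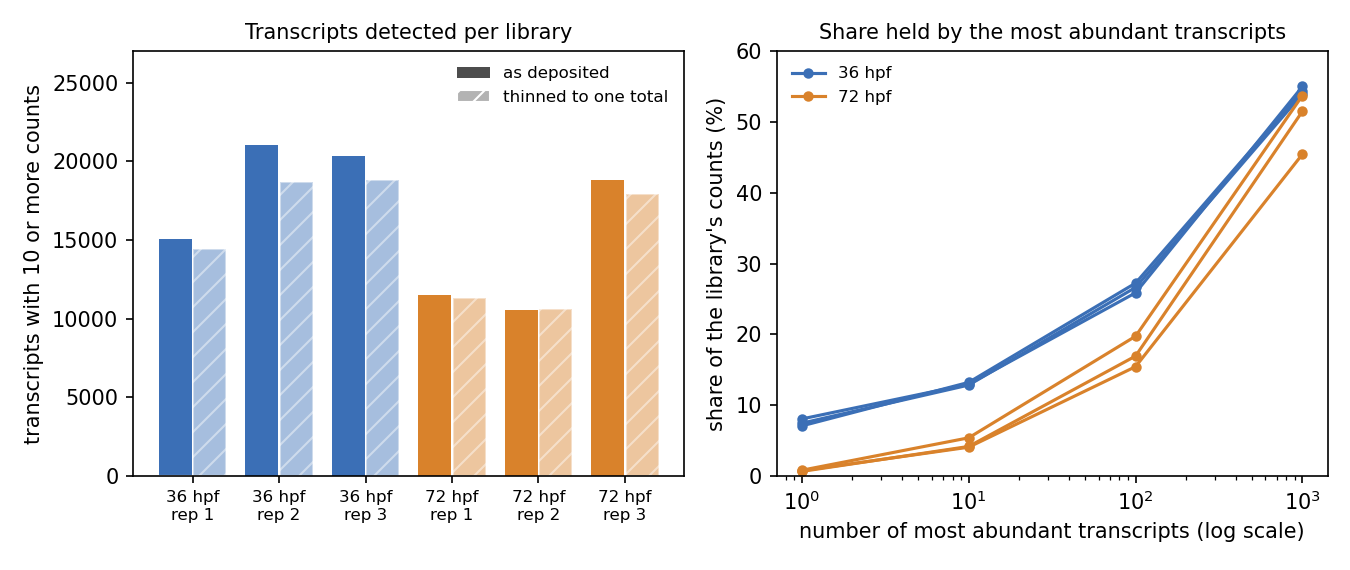
Left, bars give the number of transcripts with 10 or more estimated counts in each library, as deposited (solid) and after thinning to 7123170 counts (hatched). Right, each line is 1 library and gives the percentage of its counts held by its 1, 10, 100 and 1000 most abundant transcripts on a log axis; the 36 hpf lines (blue) begin at 7.04 to 8.02% and the 72 hpf lines (orange) at 0.601 to 0.771%.

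Libraries of the same stage shared most of their abundant transcripts. Of the 100 most abundant transcripts, pairs of 36 hpf libraries shared 71 to 84 and pairs of 72 hpf libraries shared 61 to 73, while pairs from different stages shared 31 to 44. Over all 17711 tested transcripts the separation was less complete. Pearson's r of log2(CPM + 1), taken across transcripts, which are not independent replicates, was 0.639 to 0.793 within 36 hpf, 0.370 to 0.481 within 72 hpf and 0.293 to 0.499 between the stages. The ranges within 72 hpf and between stages overlapped. On the first principal component, which held 39.6% of the variance, replicates 1 and 2 at 72 hpf lay at 250.3 and 323, replicate 3 at -32.6, and the 36 hpf libraries between -185 and -173.

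**Figure D2:**
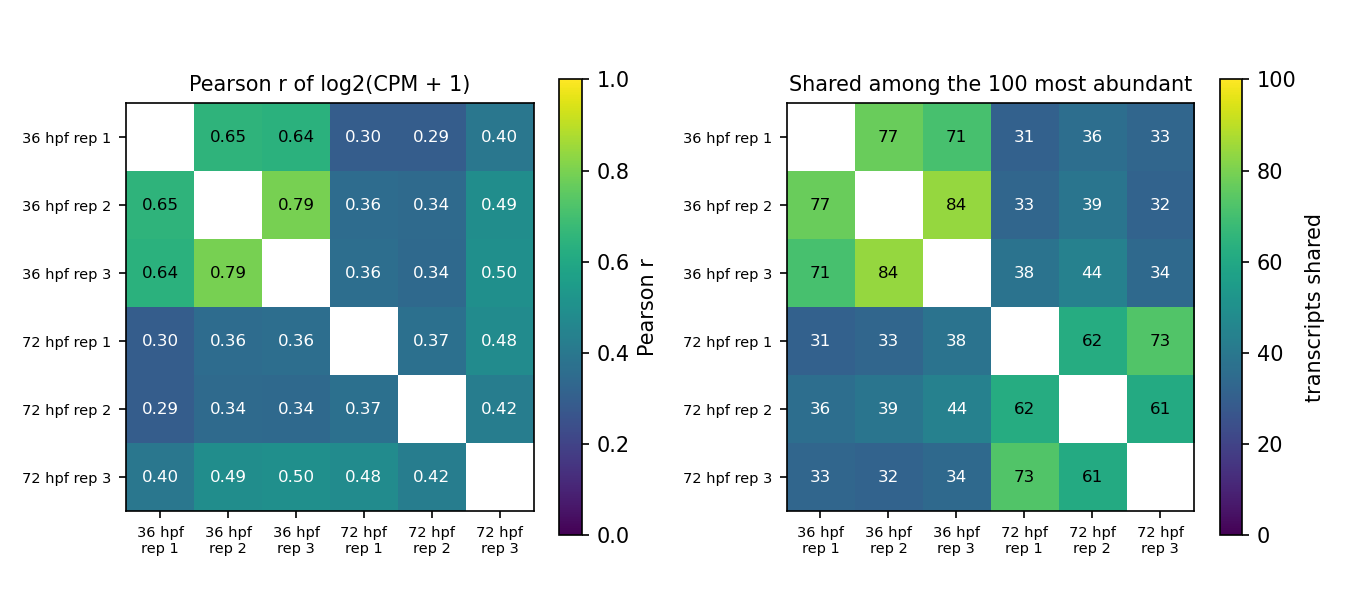
Each cell compares 2 of the 6 libraries. Left, Pearson's r of log2(CPM + 1) over the 17711 tested transcripts; right, the number of transcripts shared between the 100 most abundant of each library, which is 31 to 44 for pairs from different stages and 61 or more for pairs of the same stage.

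Of the 17711 transcripts tested, 37 rose and 35 fell from 36 to 72 hpf by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The 37 that rose together made up 0.328% ± 0.0048 of the counts at 36 hpf and 3.83% ± 0.107 at 72 hpf (SD, n = 3). The 35 that fell made up 10.8% ± 0.33 at 36 hpf and 0.378% ± 0.264 at 72 hpf (SD, n = 3). These sums describe transcripts already selected by the test and are not separate evidence of the change. In all 72 the libraries of the stages did not overlap, as held for 4098 tested transcripts (23.1%). Interchangeable libraries would give 10% on average over splits, but these libraries differed in detection. The share was not computed for other splits, so the 23.1% cannot be credited to stage. The smallest change among the 72 was 1.74 on the log2 scale. In 34 of them the lower stage was under 1 CPM in all 3 libraries, at 36 hpf for 19 and at 72 hpf for 15. Counts this low may include reads transferred from other libraries, which was not decided. An unadjusted p under 0.05 was reached by 1831 transcripts, 600 higher and 1231 lower at 72 hpf. The biological coefficient of variation was 1.497, so that transcripts outside the 72 cannot be read as unchanged. The count depended on which libraries entered: it was 9, 5 and 3 without replicates 1, 2 and 3 at 36 hpf and 10 without replicate 1 at 72 hpf. Without replicate 2 at 72 hpf it was 86, and without replicate 3 at 72 hpf it was 0, where 3892 transcripts had an unadjusted p under 0.05. DESeq2 called 1581 transcripts and limma-voom 1033 on the same counts, with 31.5% and 25.6% of them higher at 72 hpf against 51.4% here.

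**Figure D3:**
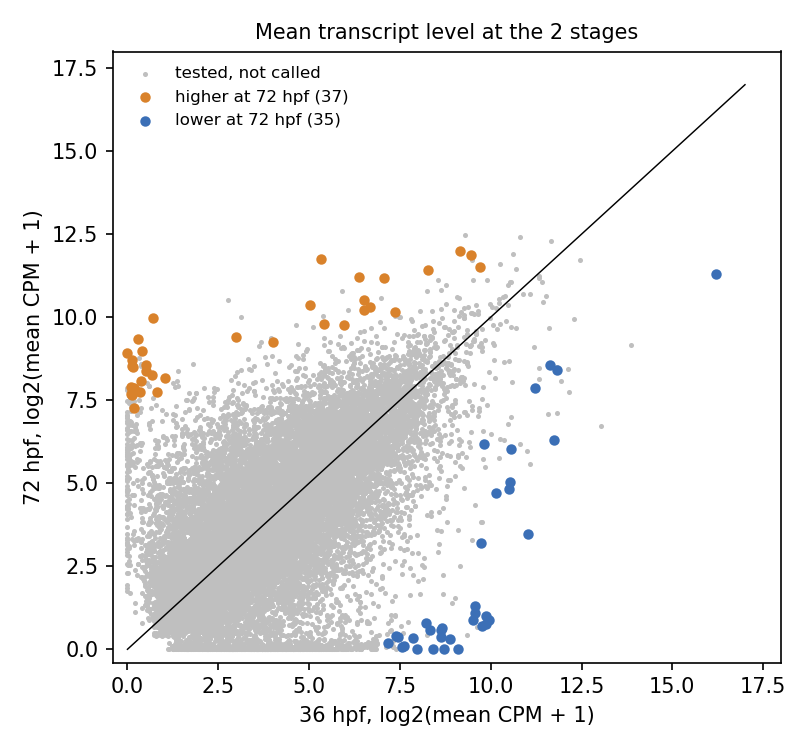
Each point is 1 of the 17711 tested transcripts, placed by log2(mean CPM + 1) over the 3 libraries at 36 hpf (horizontal) and at 72 hpf (vertical), with a line of equal level. The 37 transcripts higher at 72 hpf are orange and the 35 lower are blue; the blue point farthest to the right is the 1932-base transcript.

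Among the transcripts that rose, ENSDART00000165228.1 (4604 bases) had 0 counts in all 3 libraries at 36 hpf and 488 ± 330 CPM (SD, n = 3) at 72 hpf. This was at least 7207-fold higher against a floor of 3 counts over the 36 hpf libraries, with an adjusted p of 0.0497 by edgeR's quasi-likelihood test. ENSDART00000055936.4 (2181 bases) had 3 counts in total at 36 hpf and 365 ± 103 CPM (SD, n = 3) at 72 hpf. Its ratio of pooled levels was 5257, with a 95% counting interval of 1799 to 25490 and an edgeR adjusted p of 0.0259. The 3 counts may include reads transferred from other libraries, which was not decided, so the ratio may be only a lower bound. Of these 3 counts 2 lay in replicate 1 at 36 hpf, and without that library the ratio was 11799, with an interval of 2118 to 466021. Among those that fell, ENSDART00000066973.4 (3206 bases) went from 547 ± 231 CPM (SD, n = 3) to 0 counts in all 3 libraries at 72 hpf. It was at least 4635-fold lower against the same floor over the 72 hpf libraries, with an edgeR adjusted p of 0.0201. ENSDART00000156973.2 (5367 bases) went from 421 ± 175 CPM (SD, n = 3) to 0 and was at least 4052-fold lower, with an edgeR adjusted p of 0.0261. The reads of ENSDART00000165228.1, ENSDART00000066973.4 and ENSDART00000156973.2 were shared with other transcripts, so that an exact 0 may come from how the shared reads were assigned. The estimated counts of ENSDART00000055936.4 were whole in all 6 libraries, so its reads were counted as unshared, which whole counts do not prove. Intervals and floors cover counting error only, because reads amplified without molecular identifiers are not independent molecules. Each of the 4 lost its call in 5 of the 6 fits that left out a library and kept it only without replicate 2 at 72 hpf. The direction was the same in all 6, which was nearly certain because their libraries did not overlap between the stages. Over all other fits, ENSDART00000165228.1 passed the threshold in 9 of 16, ENSDART00000055936.4 in 11 of 17, and ENSDART00000066973.4 and ENSDART00000156973.2 in 10 of 16 each. All 4 lost their call with the replicate number as a block, with edgeR adjusted p from 0.125 to 0.163. ENSDART00000165228.1 also lost its call in the robust edgeR fit, with an adjusted p of 0.0510, in a range over its fits of 5.25e-13 to 0.164. The lower bounds move with the library totals: that of ENSDART00000165228.1 was 4046 without replicate 2 at 36 hpf, and without replicate 3 at 72 hpf those of ENSDART00000066973.4 and ENSDART00000156973.2 were 2701 and 2361.

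3 abundant transcripts were singled out after their values were seen. They were taken from the 3 most abundant of each stage and the most abundant one called higher, and the rest did not pass the threshold. At 36 hpf the rest were of 2374 and 4640 bases, 27.1-fold and 83.9-fold lower at 72 hpf, with edgeR adjusted p of 0.0694 and 0.0516. At 72 hpf they were of 2358 and 1551 bases, with edgeR adjusted p of 0.163 and 0.870. The 1932-base transcript fell from 74956 ± 4961 CPM to 2498 ± 2332 CPM (SD, n = 3). Its log2 fold change was -4.96 (SE 0.69), or 31.0-fold lower, with an edgeR adjusted p of 0.0490, and it passed the threshold in 10 of 17 other fits, whose adjusted p ranged from 0.000175 to 0.185. The size of the fold rested on replicate 2 at 72 hpf: without it the log2 fold change was -6.09, with an edgeR adjusted p of 0.00567. Leaving out any of the other 5 libraries ended the call. Whether its reads were shared was not decided at 36 hpf, where its counts are too high for decimals to be written in all 3 libraries. A 1950-base transcript, whose reads were shared, rose from 572 ± 69 to 4039 ± 373 CPM (SD, n = 3). Its log2 fold change was 2.76 (SE 0.21), or 6.79-fold higher, with an edgeR adjusted p of 0.00916. It passed the threshold in 12 of 16 other fits, whose adjusted p ranged from 0.000503 to 0.0700, and lost its call in 4 of the 6 fits that left out a library. A 1699-base transcript had the highest mean level at 72 hpf, at 5650 ± 1221 CPM against 627 ± 435 CPM at 36 hpf (SD, n = 3). Its log2 fold change was 3.11 (SE 0.56), and with an edgeR adjusted p of 0.0882 it did not pass the threshold, though it was higher in 3 of 3 libraries.

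The abundant transcripts of each stage were also followed into the other stage. At 36 hpf 148 transcripts reached 500 CPM in all 3 libraries, and at 72 hpf 119 did, with 50 in both sets. The median of the 148 was at 31.9% of its 36 hpf level at 72 hpf, and the median of the 119 was at 42.9% of its 72 hpf level at 36 hpf. With a minimum of 200 CPM the order turned round, at 51.2% and 47.3%, and with 1000 CPM the medians were 24.6% and 41.1%. Of the 148, 19 were under 5% of their 36 hpf mean in all 3 libraries at 72 hpf, and 19 were called lower by edgeR. Of the 119, 8 were under 5% in all 3 libraries at 36 hpf, and 15 were called higher at 72 hpf. The 36 hpf share depended on the minimum: it was 12.8% at 500 CPM, 7.06% (35 of 496) at 200 CPM and 11.1% (6 of 54) at 1000 CPM, minimums chosen after the data were seen. The 72 hpf share was 6.72, 5.85 and 7.69% at the same minimums. Sets chosen for a high level in one stage fall on average in the other by selection alone, and the difference between the 2 sets was not tested.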

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

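The tests of unshared transcripts only and of those at 100 CPM or more, and the other numbers of top transcripts, were chosen after the results were seen. Against 72 called transcripts (37 higher, 35 lower at 72 hpf), the count was 174 (82 and 92) with no filter, 920 (236 and 684) with the stricter filter, 1581 (498 and 1083) by DESeq2, 1033 (264 and 769) by limma-voom and 882 (270 and 612) by limma-trend on TPM. It was 14 (4 and 10) at an adjusted p under 0.01, 44 (20 and 24) among 3658 unshared transcripts and 258 (136 and 122) among 3097 transcripts at 100 CPM or more at a stage. The stricter filter, which asks for 1 CPM in every library of a stage and a mean of 10 counts, left 12888 transcripts; the cause of these differences was not tested. DESeq2 gave no adjusted p for 1223 transcripts, and on simulated unchanged transcripts it made 314 calls where edgeR made 0. As the simulation used edgeR's own dispersions, it does not show which count is nearer the truth in the data. The count was within 1.5 times of 72 with relative log expression factors (60), library size only (76), the robust fit (83) and a log2 fold change of at least 1 (72). Relative log expression factors and library size only moved the median log2 fold change of all tested transcripts by 0.15 and 0.10. Larger shifts came with limma-voom (-1.04), the replicate block (-0.83), limma-trend on TPM (-0.39) and the minimum of 100 CPM (0.33).

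Leaving out 1 library gave 0 to 86 calls, 0 to 25 of them higher and 0 to 61 lower. It was 0 without replicate 3 at 72 hpf, where 3892 transcripts had an unadjusted p under 0.05, and 86 without replicate 2 at 72 hpf; the values without replicates 1, 2 and 3 at 36 hpf and replicate 1 at 72 hpf were 9, 5, 3 and 10. Of the 72, all kept their direction in each fit that tested them, which was nearly certain because their libraries did not overlap between the stages. Of the same 72, 71 were also called by DESeq2, 56 by limma-voom and 72 with the stricter filter, which uses the stage labels. With the replicate number as a block the count was 23 (7 and 16), 21 of them among the 72. Deviations of same-numbered libraries correlated at 0.0075, -0.013 and 0.037, and not every library correlated best with its own number, so the numbers were not taken as pairs.

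The mean correlation between stages, 0.375 over all tested transcripts, was -0.504 over the 500 most variable, which are chosen for differing. Within 72 hpf the mean was 0.424, and 0.491 with a pseudocount of 5 CPM; leaving out 1 library gave 0.370 to 0.481, and within 36 hpf 0.639 to 0.793 around 0.694. Pairs from different stages shared on average 35.6% of their top 100 transcripts, 30.4% of the top 50 and 36.7% of the top 500; within 72 hpf this was 65.3, 67.3 and 55.2%. Gene list tests, the sorting genes and alternatives per named gene symbol were not run, because transcripts were not paired with genes. Depth limits the lowest levels: where a stage was at 0, a fold was only a bound against 3 counts over its libraries.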

Other observations

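Transcripts present in one stage and at 0 in the other were more numerous for 36 hpf. With 10 or more counts in all 3 libraries of a stage and 0 in all 3 of the other, 424 transcripts were found at 36 hpf only and 58 at 72 hpf only, 482 in all. The split that set replicate 1 at 36 hpf with replicates 1 and 2 at 72 hpf against the other libraries gave 489, nearly all at 0 in those 3 libraries (482). These 3 are the libraries in which the fewest transcripts were detected, so the number at 36 hpf only cannot be read as a number of genes switched off.

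The tests on replicate 2 at 72 hpf, the splits, and the intervals put on each test were chosen after the results were seen. Detection differed most within 72 hpf, where the highest library had 1.78 times as many transcripts at 10 counts as the lowest. Library depth as the whole cause is argued against, since the ratio was 1.70 after thinning to one total (1.70 in each of 20 repeats, to 3 digits). A few transcripts taking most of the counts is argued against too, since the 100 most abundant of each 72 hpf library held 15.4 to 19.7% of its counts. Without the 100 of highest mean CPM over the 6 libraries the ratio was 1.69 (1.69 to 1.70 over repeats). With shares this low, that removal was a weak test. The number of cells or the RNA input of each sample stays open and was not tested, as the labels give only a range, and so does a biological difference between the samples.

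Of the 547 to 669 unshared transcripts per library with 5000 or more counts in the other libraries together, 2.56 to 29.0% were at under 3 counts per 1000 of those, including 1 to 22 at 0. A transfer of reads between libraries would give a constant share, and among transcripts with 2000 to 5000 counts elsewhere the share was 0.424 to 0.513 per 1000 over the 6 libraries, against 0.394 to 0.764 at 5000 or more; in the 4 libraries with at least 3 transcripts at 20000 or more, the share there was 0.436 to 1.34, within 2 times in 2 and outside in 2. Low-level expression in the cells would vary between transcripts, and the median variance index was 8.12, above 3 in 5 of 6 libraries. By these values alone, under limits set before the test but after the distribution of these shares had been viewed, transfer would have been excluded and low-level expression retained; bootstrap intervals, added after that outcome was seen, put 0 of the 4 libraries outside 2 times and 2 of 6 above 3. With the intervals neither is decided, and the explanations may also act together.

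The 20 transcripts most abundant at 36 hpf were each highest, among the 72 hpf libraries, in replicate 2, with medians of 6.93, 17.45 and 4.09% of their 36 hpf level in replicates 1, 2 and 3, while over all 148 transcripts abundant at 36 hpf the medians were 28.0, 34.6 and 33.7%. Mixing of 36 hpf cDNA into that library would carry all abundant 36 hpf transcripts at about the share of the most abundant one, 6.92%. That share includes what the library would hold without mixing, and the same transcript was at 1.76% and 1.33% in replicates 1 and 3. Mixing is argued against as the whole cause, because 17.6% of the 148 (exact 95% binomial interval 11.8 to 24.7%) lay below 3.46%, the limit set at 50% of the 6.92% share, as did 27.0 and 25.0% in replicates 1 and 3. A minority of cells holding these transcripts in their 36 hpf proportions would meet the same objection, so these tests do not tell it apart from mixing. The binomial interval treats the 148 transcripts of 1 library as independent, which they are not. Of the 148, 44 had unshared reads, and 7 of these 44 lay below the limit in replicate 2. Low values of the others may come from how shared reads were assigned. Cells only partly like those at 36 hpf stay open: of 12 transcripts under 1% in both other 72 hpf libraries, 3 (25%, interval 5.49 to 57.2%) reached 1% in replicate 2. These hypotheses were formed on the data that tested them.

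For the comparison of the stages, 1 of the 10 splits of the 6 libraries, the real one, gave as many transcripts by edgeR: 72, with 0 as the highest of the others. By limma-voom the real split gave 1033 and the highest other 566, for the same grouping of replicate 1 at 36 hpf with replicates 1 and 2 at 72 hpf, the 3 libraries in which the fewest transcripts were detected; the cause was not tested. With 10 splits no share under 0.05 can be reached. Splits by DESeq2 were not run. The difference between the mean correlation within and between groups was 0.184 for the real split and 0.0136 for the highest other. It pools both stages, with means of 0.694 within 36 hpf, 0.424 within 72 hpf and 0.375 between the stages. Replicate 3 at 72 hpf correlated at 0.395, 0.490 and 0.499 with replicates 1, 2 and 3 at 36 hpf. With replicates 1 and 2 of its own stage it correlated at 0.481 and 0.422. The pooled value therefore does not show that the 72 hpf libraries resemble one another.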
